A study of Arabidopsis thaliana with 9 samples.

How the data were processed

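Poly(A) RNA-seq libraries were analysed from 9 Arabidopsis seedling samples, 3 of each genotype, all exposed to 100 µM cadmium for 6 h. Per the labels' protocols, total RNA was isolated with TRIzol and libraries were made with a SMARTer mRNA kit. Per the submitters' processing notes, the builds GRCm38 and mm10 are named, which are mouse builds. The gene identifiers and positions in the deposited table are those of Arabidopsis: of 26973 genes, 26513 matched a locus of the TAIR10.1 annotation (RefSeq) and 26504 of these, 99.966%, had the same start and end. The remaining 460 genes had no match. Coordinates are given in TAIR10.1. The aligner, the counting program and the handling of strand and of reads shared between genes are not given in the sources used here.

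The deposited values are FPKM; no label or header names the unit, which was inferred from the values. Multiplied by exon length they sum to about the same total in every sample, as FPKM made by the authors from counts over all genes would. There were 3 deposited tables with identical content, so 1 was used. Within each library, low values multiplied by exon length fell on multiples of 1 step (tolerance 0.05 of a step), of which 4 make 1 unit, a read or a fragment, in 99.4% to 99.6% of low values. Whole units alone held 42.3% to 44.9% of them, so the values are not whole counts and no count model was used. The totals rebuilt from these steps are 12.7, 17.2 and 15.1 M units in wild type, 17.1, 15.6 and 16.4 M in OXmiR400 and 21.1, 20.4 and 19.3 M in OXrPPR1. A gene listed at 0 can be a failed estimate, so some such genes are given per library. Means of other genes can include a value of 0.

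The planned tests named limma for normalized units, and it was used. Genes with a mean of at least 1 FPKM in at least 1 genotype were kept (19955), values were transformed to log2(FPKM + 1), and 1 linear model over the 3 genotypes was fitted to all 9 libraries in limma 3.58.1 (R 4.3.3), with a trended, robust empirical Bayes variance and Benjamini-Hochberg adjustment. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Genes were called at adjusted p under 0.05, in either direction. At unadjusted p under 0.05 there were 3172, 2098 and 1478 genes in the comparisons of OXmiR400 with wild type, OXrPPR1 with wild type and OXmiR400 with OXrPPR1, where 997.8 are expected by chance.

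Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 23 of 24 lists with at least 5 tested members. The lists were Rf-like PPR genes, organelle RNA editing cofactors, mitochondrial retrograde response, alternative respiratory chain, metal chelation and transport, iron deficiency, sulfate assimilation and glutathione synthesis, glutathione S-transferases, heat shock, reactive oxygen metabolism, abscisic acid and dehydration, salicylic acid and camalexin, jasmonate, ethylene, endoplasmic reticulum stress, anthocyanin and flavonol synthesis, glucosinolate synthesis, nuclear photosynthesis genes, root markers, seed storage and oil body markers, dividing cell markers, circadian clock, and the mitochondrial and plastid genomes. Camera called 9, 4 and 5 lists in the 3 comparisons. With a correlation estimated from the residuals it called 0, 0 and 0, where 3, 2 and 1 had an unadjusted p under 0.05. At the preset correlation, wrong groupings of the 6 libraries of a comparison gave up to 9, 8 and 10 lists. The directional test of fry, which does not compare a list with other genes, called 4, 0 and 0 lists (5, 4 and 2 unadjusted), and its test for change in either direction 10, 6 and 1.

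Grouping, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named the 4 loci of the labels and targets; among called genes with an absolute log2 fold change of at least 1, libraries that do not overlap, a mean of at least 2 FPKM in the higher genotype and a symbol or product name, the 6 largest rises and 6 largest falls; and up to 4 members of each called list. How a product name was read, leaving out entries such as ncRNA or hypothetical protein without a symbol, was settled after the values were seen, and genes called in both lines or outside the rule were named after their values were seen. The method was tested on simulated data for OXmiR400 against wild type with at least 19494 genes in each of 3 data sets. Over these sets together, of 300 changes of 2-fold 228 were called (76%) and of 300 of 4-fold 289 (96.3%), with 19 false calls, and a list shifted in another simulation was called with 0 others (camera). The changed genes had a mean of at least 5 FPKM and genes were simulated as independent.

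Alternatives were quantile normalization, median centring, no variance trend, no filter, a stricter filter of 5 FPKM, a pseudocount of 0.1, only the 6 libraries compared, the replicate number as a block, organelle genes left out, and each of the 9 libraries left out in turn. Voom on the rebuilt units, which did not include organelle genes, was added after the data were seen.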

Results

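RNA-seq was performed on Arabidopsis thaliana seedlings of 3 genotypes, wild type and the lines labelled OXmiR400 and OXrPPR1, with 3 libraries per genotype. Seedlings of all 9 libraries had been exposed to 100 µM cadmium, a toxic heavy metal, for 6 h. No library without cadmium was analysed here, so the values compare genotypes after exposure and give no effect of the metal itself. Expression was given as FPKM, fragments or reads per kilobase of exon, scaled to library size. Depth rebuilt from the steps between low values was 12.7 to 17.2 M units in wild type, 15.6 to 17.1 M in OXmiR400 and 19.3 to 21.1 M in OXrPPR1, a unit being a read or a fragment. The labels do not say that libraries of a genotype came from separate cultures, so p-values measure the spread between these samples, which may be technical.

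Libraries of a genotype correlated at r = 0.962 to 0.981 across genes on the log2 scale, and libraries of different genotypes at 0.95 to 0.974, where genes are not independent replicates. On the first principal component, with 24.9% of the variance, the wild type libraries lay at -36.2, -11 and -26.7 and the OXmiR400 libraries at 16.6, 25.4 and 20.8. OXrPPR1 replicate 3 lay at -16.8, apart from OXrPPR1 replicates 1 and 2 at 9.9 and 18.1. On the second component (18.3%), wild type replicate 2 at -22.2 lay near OXrPPR1 replicates 1 and 2, at -20.6 and -28.3. Wild type replicate 2 correlated at 0.9745 with OXrPPR1 replicate 1, and at 0.9643 and 0.9698 with wild type replicates 1 and 3. OXrPPR1 replicate 3 correlated at 0.9681 and 0.9705 with wild type replicates 1 and 3, and at 0.9649 and 0.9621 with OXrPPR1 replicates 1 and 2. Plastid genes took 0.3%, 0.46% and 0.37% of the units in the wild type libraries, 0.27%, 0.11% and 0.19% in OXmiR400 and 0.12%, 0.1% and 0.13% in OXrPPR1.

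The loci named by the genotype labels were examined first. MIR400 (AT1G32582), the precursor of the microRNA miR400, lies on chromosome 1 at 11785936 to 11786037 on the plus strand (TAIR10.1). It sits inside intron 1 of the 3 introns of the host gene AT1G32583, an intron at 11785917 to 11786222 that precedes the first coding base at 11787351. MIR400 was listed at 953, 684 and 629 FPKM in the OXmiR400 libraries, against 0.194, 0.572 and 0 FPKM in the wild type libraries. It rose by a log2 fold change of 9.24 ± 0.21 (SE, adjusted p = 1.15e-08 in limma), a size that depends on the pseudocount because wild type values lie near 0. In OXrPPR1 it averaged 0.196 ± 0.178 FPKM (SD, n = 3) and did not differ detectably from wild type (adjusted p = 0.951). The host gene AT1G32583 measured 2.56 ± 0.35, 3.195 ± 0.339 and 2.78 ± 0.578 FPKM (SD, n = 3) in wild type, OXmiR400 and OXrPPR1, with adjusted p = 0.509 and 0.893 for the lines against wild type. The precursor overlaps its host, so reads of the pair may be shared, and the locus is listed again under another identifier, with nearly the same values in OXmiR400, so that it counts as 2 genes in the totals for that line.

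PPR1 (AT1G06580) and PPR2 (AT1G62720) encode pentatricopeptide repeat proteins, organelle RNA-binding proteins, and are known targets of miR400. PPR1, on chromosome 1 at 2013996 to 2016273 on the minus strand, measured 24.0 ± 1.87 FPKM in OXrPPR1 and 2.37 ± 0.186 FPKM in wild type (SD, n = 3). The rise was 2.89 ± 0.16 on the log2 scale (SE, adjusted p = 5.12e-05 in limma), and reads of a transgene and of the endogenous gene cannot be separated in these values. In OXmiR400, PPR1 measured 2.001 ± 0.615 FPKM (SD, n = 3), a log2 fold change of -0.19 ± 0.16 (SE) that did not pass (adjusted p = 0.613 in limma). It was -0.32 without OXmiR400 replicate 1 and -0.02 without OXmiR400 replicate 3, called in neither (adjusted p = 0.412 and 0.972). PPR2 lay below the expression filter in all genotypes, at 0.724 ± 0.358, 0.468 ± 0.043 and 0.615 ± 0.088 FPKM in wild type, OXmiR400 and OXrPPR1 (SD, n = 3). With no filter its log2 fold change in OXmiR400 was -0.21 ± 0.15 (SE, adjusted p = 0.596 in limma).

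**Figure D1:**
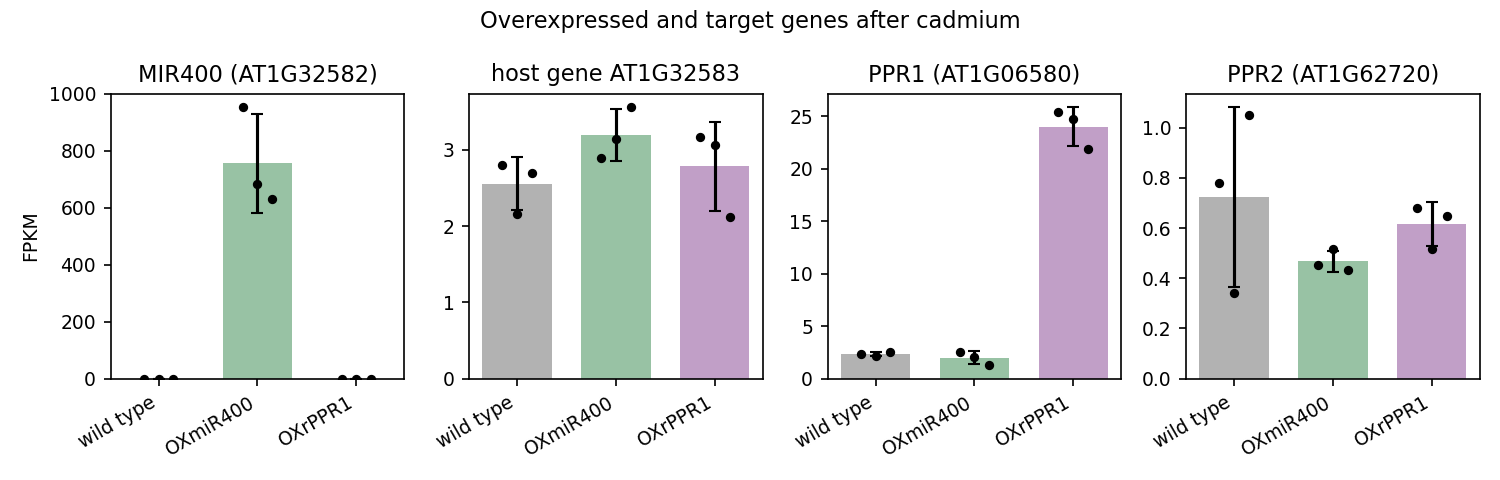
FPKM (vertical axes, linear, from 0) of MIR400, its host gene, PPR1 and PPR2 in the 3 genotypes; bars are means, error bars SD, and points the 3 libraries of each genotype. MIR400 stands at 629 to 953 FPKM in OXmiR400 and PPR1 averages 24.0 FPKM in OXrPPR1.

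The first comparison asks which transcripts differed between the line with high MIR400 and wild type after cadmium. Of 19955 genes tested, 43 were higher and 71 lower in OXmiR400, 114 in all at adjusted p under 0.05, and 67 of them changed by at least 1 on the log2 scale. Genes that rose besides MIR400 included AT5G37490, an ARM repeat protein, from 1.38 ± 0.737 to 12.1 ± 1.35 FPKM, and AT2G18190, a nucleoside triphosphate hydrolase, from 0.478 ± 0.121 to 6.19 ± 2.17 FPKM (SD, n = 3). The late embryogenesis abundant protein gene AT3G53040 rose by 1.98 ± 0.31 and GRP5 (AT3G20470), a glycine-rich protein, by 1.93 ± 0.32 (log2, SE). AT3G02620, a stearoyl-acyl-carrier-protein desaturase, rose by 1.76 ± 0.17 (log2, SE). In OXrPPR1, AT5G37490 measured 6.86 ± 2.70, AT2G18190 3.83 ± 1.41, AT3G53040 4.16 ± 1.55 and GRP5 27.7 ± 8.65 FPKM (SD, n = 3). These genes were not called between the lines (adjusted p = 0.556 to 0.994 in limma), while AT3G02620 was (0.0101). Genes that fell included SDI1 (AT5G48850), a gene induced by sulfur deficiency, from 148 ± 78.4 to 15.2 ± 2.15 FPKM, and DIN2 (AT3G60140), a glycosyl hydrolase, from 62.2 ± 29.2 to 10.2 ± 4.46 FPKM (SD, n = 3).

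MRD1 (AT1G53480) fell by 2.41 on the log2 scale, AT3G05170, a phosphoglycerate mutase family gene, fell by 2.21, and SPX1 (AT5G20150), a phosphate-sensing SPX domain gene, fell by 1.82, with standard errors of 0.38, 0.21 and 0.26. GGPS1 (AT4G36810), geranylgeranyl pyrophosphate synthase 1, was listed at 24.8, 12.6 and 7 FPKM in wild type and at 0 in the 3 OXmiR400 libraries. It overlaps another gene, AT4G36808, and reads of the pair may be shared. The adjusted p-values of these 12 genes in limma lay between 1.15e-08 and 0.0409. In each the 3 libraries of the higher genotype all exceeded the 3 of the lower, as the rule for named genes required. The same held for all 114 called genes and for 24.3% of tested genes, where chance gives 10%. Of the 22 named genes called in this comparison, 3 (MIR400, AT3G02620 and AT3G05170) stayed called without any 1 library and no sign turned. Of the 22, 10 stayed called without wild type replicate 1, 16 and 11 without replicates 2 and 3, 4, 4 and 8 without OXmiR400 replicates 1, 2 and 3, and 19, 19 and 22 without OXrPPR1 replicates 1, 2 and 3. The count of 114 became 36 and 42 without wild type replicates 1 and 3, 9, 8 and 25 without OXmiR400 replicates 1, 2 and 3, and 194 without OXrPPR1 replicate 3. Those left without OXmiR400 replicates 1, 2 and 3 were 5, 6 and 14 higher and 4, 2 and 11 lower. The count was 216 with only the 6 libraries compared and 66 with no expression filter. Over the 3 comparisons, 14 of the 33 calls of named genes other than MIR400 and PPR1 were lost with no filter and 5 without the variance trend.

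Sulfate assimilation and glutathione synthesis genes lay lower in OXmiR400, with a median log2 fold change of -0.51 and 24 of 27 tested members below 0. None rose, 3 fell and 24 were not called, and adjusted over the list alone 12 fell. Voom called 3 lower. The members called were SULTR1;2 (AT1G78000), a root sulfate uptake transporter, from 65.2 ± 11.9 to 26.7 ± 1.305 FPKM, LSU2 (AT5G24660), a gene responsive to low sulfur, from 118 ± 46.5 to 31.7 ± 7.41 FPKM, and SDI1 (SD, n = 3). These are a transporter and sulfur-deficiency genes, not enzymes of the pathway. BGLU28, a glucosidase gene, measured 75.3 ± 49.4 and 8.92 ± 0.464 FPKM (SD, n = 3) but did not pass (adjusted p = 0.0541 in limma), and LSU1 had the opposite sign, at 2.74 ± 1.43 (log2, SE, adjusted p = 0.406). The list was called by camera (adjusted p = 9.44e-10), and not with an estimated correlation (adjusted p = 0.359). SULTR1;2 lost its call without OXmiR400 replicate 1 or 2 (adjusted p up to 0.0781), SDI1 also without wild type replicate 1 or OXmiR400 replicate 3 (up to 0.0961), and LSU2 without any library except wild type replicate 2 and OXrPPR1 replicate 3 (up to 0.146).

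Root markers, like the sulfate genes, lay lower in OXmiR400. Their median log2 fold change was -0.51 over 14 members in OXmiR400, of which 10 were below 0, none was called in limma, 6 were lower at unadjusted p under 0.05, and 4 were lower adjusted over the list alone (0 called by voom). Examples were the Casparian strip genes CASP1 (AT2G36100), at 28.0 ± 1.92 and 15.2 ± 0.716 FPKM in wild type and OXmiR400, and CASP2 (AT3G11550), at 9.25 ± 0.758 and 5.07 ± 0.272 FPKM (SD, n = 3). The peroxidase genes PRX73 and PRX44 measured 10.5 ± 4.69 and 5.85 ± 2.55 FPKM in wild type and 4.09 ± 0.197 and 1.92 ± 0.314 FPKM in OXmiR400 (SD, n = 3). The list was called by camera (adjusted p = 0.0349) but not with an estimated correlation (adjusted p = 0.663), nor without wild type replicate 3 (0.141, median -0.25) or OXmiR400 replicate 1 (0.0882). Per library, the mean log2 value of the root markers was 2.85, 2.58 and 3.14 in wild type and 2.41, 2.42 and 2.37 in OXmiR400, and that of the sulfate list 5.56, 5.07 and 5.82 in wild type and 4.84, 4.82 and 4.79 in OXmiR400. In OXrPPR1 replicates 1, 2 and 3 the root markers averaged 2.75, 2.53 and 3.05 and the sulfate list 5.11, 5.54 and 5.38, so the library with the lowest root mean of that line had its highest sulfate mean.

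Iron deficiency genes lay higher in OXmiR400, with a median log2 fold change of 0.81 and 14 of 18 tested members above 0. The 3 that rose were IMA3 (AT2G30766), from 2.27 ± 1.01 to 21.5 ± 4.64 FPKM, IMA2 (AT1G47395), from 3.42 ± 1.45 to 27.9 ± 5.45 FPKM, and NAS4 (AT1G56430), nicotianamine synthase 4, from 3.40 ± 0.619 to 10.9 ± 2.59 FPKM (SD, n = 3). IMA genes encode small peptides that promote iron uptake, and reads of near-identical copies may have been split between them. None fell and 15 were not called, and adjusted over the list alone 9 rose and 2 fell. Voom called 1 of the 18 higher and 0 lower. The phloem transporter gene OPT3 measured 24.4 ± 4.16 and 53.2 ± 4.25 FPKM in wild type and OXmiR400 (SD, n = 3, adjusted p = 0.0636 in limma). The list was called by camera (adjusted p = 1.24e-06) but not with an estimated correlation (adjusted p = 0.230). IMA3 lost its call without OXmiR400 replicate 1 or 2 (adjusted p up to 0.0760), IMA2 also without OXmiR400 replicate 3 or wild type replicate 1 or 3 (up to 0.115), and NAS4 without any 1 library of these 2 genotypes (up to 0.174).

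**Figure D2:**
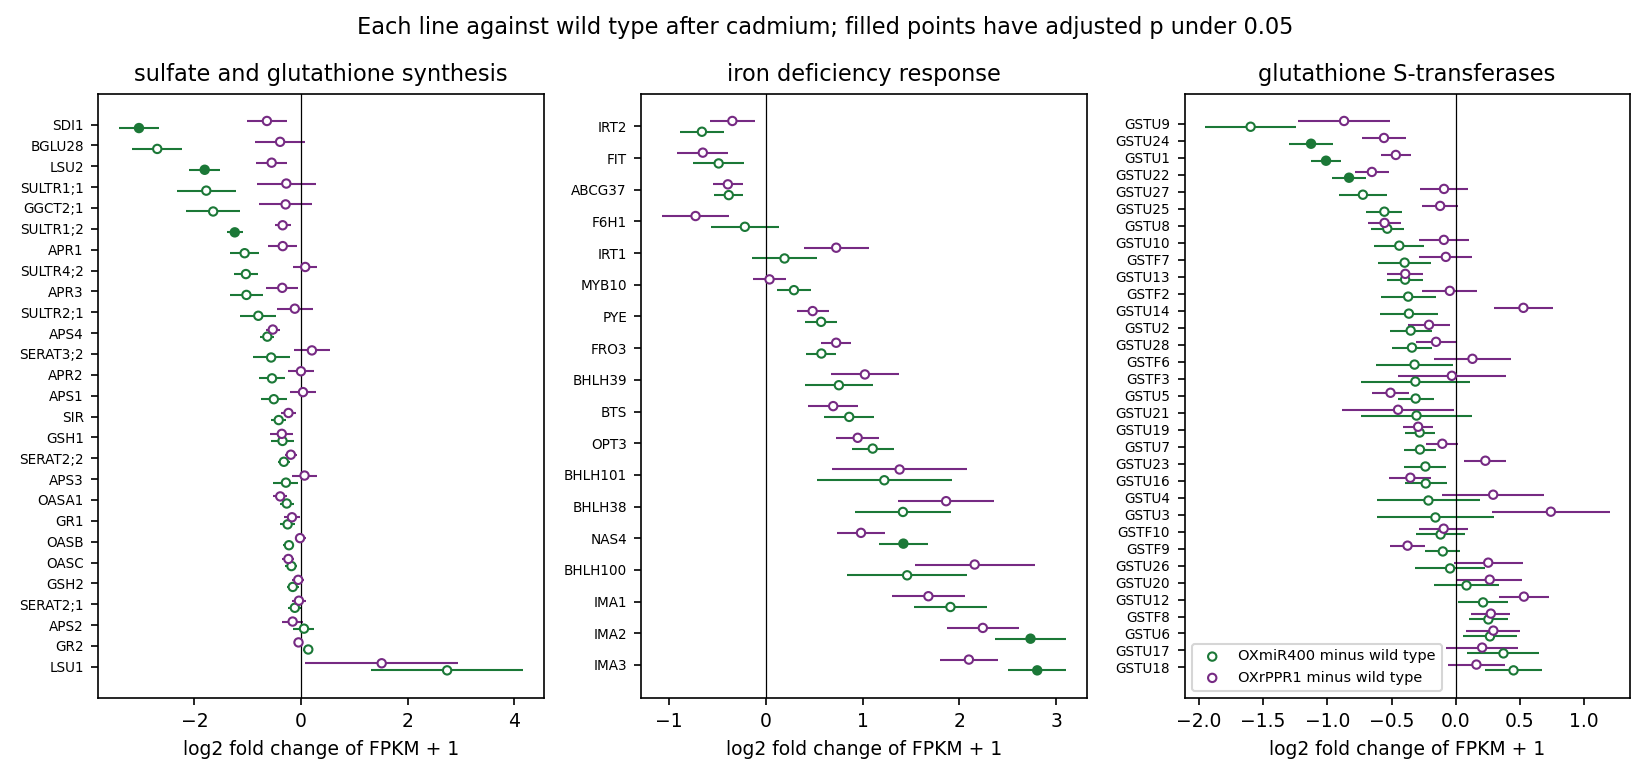
Log2 fold change of FPKM + 1 (horizontal axes, mean and SE) for members of 3 gene lists in OXmiR400 (green) and OXrPPR1 (purple), each minus wild type; filled points passed at adjusted p under 0.05. SDI1, LSU2 and SULTR1;2 lie at -3.04, -1.81 and -1.24 in OXmiR400, and IMA3, IMA2 and NAS4 at 2.81, 2.74 and 1.42.

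Glutathione S-transferase genes, which code for detoxifying enzymes, lay lower in OXmiR400 by a median of -0.31 on the log2 scale, with 27 of 33 members below 0. GSTU1 (AT2G29490) fell from 34.8 ± 3.68 to 16.7 ± 0.69 FPKM, GSTU24 (AT1G17170) from 38.5 ± 9.41 to 16.7 ± 0.254 FPKM and GSTU22 (AT1G78340) from 14.4 ± 1.29 to 7.63 ± 0.474 FPKM (SD, n = 3). None rose, 30 were not called, and adjusted over the list alone 7 fell, and voom called 2 lower. GSTU9 measured 56.2 ± 32.1 and 15.97 ± 0.49 FPKM (SD, n = 3, adjusted p = 0.0891 in limma). Reads of similar members may have been shared. Camera gave adjusted p = 3.86e-05 for the list, and adjusted p = 0.230 with an estimated correlation. GSTU1 lost its call without OXmiR400 replicate 1 or 2 (adjusted p up to 0.0781), and GSTU24 and GSTU22 also without OXmiR400 replicate 3 or wild type replicate 1 or 3 (up to 0.132 and 0.149).

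Metal chelation and transport genes had a median log2 fold change of -0.26 in OXmiR400 over 22 members (0 called in limma, 6 lower at unadjusted p under 0.05, 0 adjusted over the list alone, 0 by voom). Camera called the list (adjusted p = 0.00727), but not with an estimated correlation (adjusted p = 0.230). Its members with the smallest p were the vacuolar phytochelatin transporters ABCC2 and ABCC1, metallothionein MT2A and PCR2, a plasma membrane cadmium resistance gene. ABCC2 measured 11.5 ± 1.14 and 8.18 ± 1.02 FPKM, ABCC1 30.8 ± 1.55 and 23.9 ± 1.56 FPKM, and MT2A 404 ± 49.9 and 283 ± 23.0 FPKM in wild type and OXmiR400 (SD, n = 3). PCR2 measured 92.3 ± 22.2 and 62.9 ± 4.55 FPKM, with libraries of the 2 genotypes that overlapped. The mitochondrial retrograde response list, genes induced when mitochondria fail, had a median of -0.25 over 22 members, of which 0 rose, 1 (GSTU24, also in the transferase list) fell, 21 were not called, and 4 fell adjusted over the list alone. ABCB4, ANAC053 and GSTU25 had log2 fold changes of -0.86, -0.43 and -0.56 and did not pass (adjusted p = 0.0600, 0.0968 and 0.103). Camera called the list (adjusted p = 0.0349) but not with an estimated correlation (adjusted p = 0.912), without wild type replicate 1 (0.797, median 0.005) or without OXmiR400 replicate 1 (0.0696), and GSTU24 was itself called in neither of these (adjusted p up to 0.132). The median was -0.39 without wild type replicate 2.

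Transcripts of the plastid genome were lower in OXmiR400 by a median of -0.88 on the log2 scale, and 87 of 89 tested were below 0. In ATCG00540 they fell from 21.8 ± 3.16 to 8.66 ± 3.10 FPKM (SD, n = 3). ATCG00560 and ATCG00570 measured 81.3 ± 8.29 and 73.1 ± 11.5 FPKM in wild type and 31.2 ± 11.2 and 30.7 ± 8.84 FPKM in OXmiR400 (SD, n = 3). 1 fell, none rose, 88 were not called, and adjusted over the list alone 65 fell. Mitochondrial genome transcripts had a median of -0.51 with 53 of 56 below 0. Of these 1 fell (ATMG00220, from 5.66 ± 1.28 to 1.59 ± 0.604 FPKM), none rose, 55 were not called and 14 fell adjusted over the list alone. The organelle lists were called by camera (adjusted p = 1.51e-29 and 9.44e-10) and not with an estimated correlation (adjusted p = 0.443 and 0.559). Nuclear photosynthesis genes went the other way, with a median of 0.26 and 28 of 31 above 0 (0 called in limma, 8 higher at unadjusted p under 0.05, 2 higher adjusted over the list alone, 0 by voom). Camera gave adjusted p = 1.65e-05, or adjusted p = 0.663 with an estimated correlation. LHCB1.2 measured 2461 ± 225 and 4216 ± 623 FPKM, LHCB2.3 155 ± 19.0 and 278 ± 73.8 FPKM, and PSAG 1283 ± 76.8 and 1759 ± 198 FPKM in wild type and OXmiR400 (SD, n = 3), and reads of light-harvesting genes may be shared between copies. ATMG00220 and ATCG00540 lost their calls without wild type replicate 2 or 3 or OXmiR400 replicate 2 or 3; ATMG00220 lost it also without OXmiR400 replicate 1, and ATCG00540 without wild type replicate 1 or OXrPPR1 replicate 1 (adjusted p up to 0.112 and 0.168).

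The remaining 14 lists tested in OXmiR400 against wild type were not called (camera adjusted p = 0.138 to 0.952), and no member of them was called in limma. Adjusted p was 0.952 for 23 Rf-like PPR genes, 0.584 for 11 organelle RNA editing cofactors and 0.922 for 10 genes of the alternative respiratory chain. It was 0.952 for 18 heat shock genes, 0.644 for 23 genes of reactive oxygen metabolism (1 lower adjusted over the list alone) and 0.870 for 12 endoplasmic reticulum stress genes (1 higher adjusted over the list alone). Hormone and defence lists gave 0.952 for abscisic acid and dehydration, 0.817 for salicylic acid and camalexin, 0.141 for jasmonate and 0.644 for ethylene. Adjusted p was 0.870 for anthocyanin and flavonol synthesis, 0.138 for glucosinolate synthesis and 0.388 for dividing cell markers (1 higher adjusted over the list alone). The circadian clock list, a marker of harvest time, gave 0.567, and adjusted over the list alone 2 members were higher and 5 lower. Camera looks for a common direction, and the test of fry for change in either direction gave adjusted p = 0.000551 for this list. A difference in harvest time between OXmiR400 and wild type thus cannot be excluded. Of the seed storage and oil body markers 1 passed the expression filter, so the list was not tested. Median and test differed in sign for heat shock (median -0.02, test up) and endoplasmic reticulum stress (median -0.03, test up). Glucosinolate genes were called without wild type replicate 3 (0.00674) or OXmiR400 replicate 1 (0.0425), and dividing cell markers without wild type replicate 2 (0.0264) or OXmiR400 replicate 2 (0.0438).

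The second comparison asks what differed in the line with high PPR1. In OXrPPR1, 4 genes were higher and 9 lower than in wild type, 13 in all of 19955 tested. Setting wild type replicates 1 and 3 and OXrPPR1 replicate 3 against the rest of these libraries called 114. The samples thus have a structure apart from genotype, which these comparisons do not separate from it. AT3G01345, an expressed protein gene on chromosome 3 at 129138 to 130749, rose from 0.073 ± 0.09 to 119 ± 11.1 FPKM (SD, n = 3), with a log2 fold change of 6.81 ± 0.13 (SE, adjusted p = 4.57e-09). GASA1 (AT1G75750), a gibberellin-regulated gene, rose from 329 ± 63.0 to 833 ± 65.1 FPKM, while AT1G60070, a gamma subunit of the AP-1 adaptor, fell from 25.9 ± 0.936 to 10.08 ± 1.805 FPKM and AT5G26270, a transmembrane protein gene, from 11.5 ± 2.55 to 4.09 ± 0.569 FPKM (SD, n = 3; adjusted p = 0.03, 0.00546 and 0.0396 in limma). The plastid genes ATCG00570, ATCG00540 and ATCG00560 fell by 1.90, 1.70 and 1.94 on the log2 scale. PPR1, AT3G01345 and AT1G60070 stayed called without any 1 library. The other 5 named genes lost their call without wild type replicate 1 or 3, OXmiR400 replicate 3, or OXrPPR1 replicate 1 or 2 (GASA1 adjusted p up to 0.109, AT5G26270 up to 0.154). GASA1 and AT5G26270 lost it also without OXrPPR1 replicate 3, and the 3 plastid genes without wild type replicate 2 (adjusted p up to 0.147). The count of 13 became 5 and 7 without wild type replicates 1 and 3, 44, 43 and 5 without OXmiR400 replicates 1, 2 and 3, and 4 and 5 without OXrPPR1 replicates 1 and 2. It was 39 with only the 6 libraries compared, 8 with no filter and 8 by voom. With replicate numbers as a block, 7 were higher and 3 lower, and 6 of the 13 stayed called.

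Plastid transcripts were lower in OXrPPR1 in 89 of 89 tested genes, by a median of -1.40 on the log2 scale. Of these 3 fell, none rose, 86 were not called, and adjusted over the list alone 84 fell. Mitochondrial transcripts had a median of -0.65, with 53 of 56 below 0. In limma 0 were called (1 higher and 33 lower at unadjusted p under 0.05; organelle genes were not tested by voom), and adjusted over the list alone 21 were lower and 1 higher. ATMG00220 measured 1.85 ± 0.072 FPKM in OXrPPR1 against 5.66 ± 1.28 FPKM in wild type, and ATMG00513 1.55 ± 0.487 against 4.67 ± 1.05 FPKM (SD, n = 3). Camera gave adjusted p = 6.93e-70 for plastid and 3.34e-17 for mitochondrial genes, and with an estimated correlation adjusted p = 0.259 and 0.374. Iron deficiency genes had a median of 0.84, with 14 of 18 above 0. In limma 0 were called (11 higher and 2 lower at unadjusted p under 0.05, 0 by voom), 11 were higher and 2 lower adjusted over the list alone. Camera gave adjusted p = 1.35e-07, or adjusted p = 0.259 with an estimated correlation. IMA3, IMA2, IMA1 and the ferric reductase gene FRO3 measured 13.3 ± 5.88, 21.5 ± 13.2, 11.8 ± 7.95 and 49.4 ± 11.1 FPKM in OXrPPR1 (SD, n = 3). The sulfate list had a median of -0.19 over 27 members (0 called in limma, 3 lower at unadjusted p under 0.05, 0 adjusted over the list alone, 0 by voom), with APS4 at -0.53 ± 0.13 and OASA1 at -0.39 ± 0.13 (log2, SE). Camera called it (adjusted p = 0.0242) but not with an estimated correlation (adjusted p = 0.935), nor without wild type replicate 1 (0.0698), wild type replicate 3 (0.714, median -0.05) or OXrPPR1 replicate 1 (0.358, median -0.10). The median was -0.29 without OXrPPR1 replicate 3. The other 19 lists were not called (camera adjusted p = 0.0791 to 0.869), and of the Rf-like PPR genes 1 rose, PPR1 itself. Adjusted over the list alone, 2 circadian clock genes and 4 glutathione S-transferase genes were lower. For these lists the test of fry for change in either direction gave adjusted p = 0.0179 and 0.0392. Median and test differed in sign for the Rf-like PPR, retrograde, endoplasmic reticulum stress, root and dividing cell lists, none of them called. Calls were gained without wild type replicate 2 for metal chelation (0.0241) and transferases (0.0241), without OXrPPR1 replicate 2 for transferases (0.0451) and the retrograde list (0.00624), and without wild type replicate 3 for glucosinolate (0.0236) and photosynthesis genes (0.0127). Photosynthesis genes were also called without OXrPPR1 replicate 3 (0.00154), and abscisic acid genes without wild type replicate 1 (0.00932) or OXrPPR1 replicate 1 (0.00876).

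**Figure D3:**
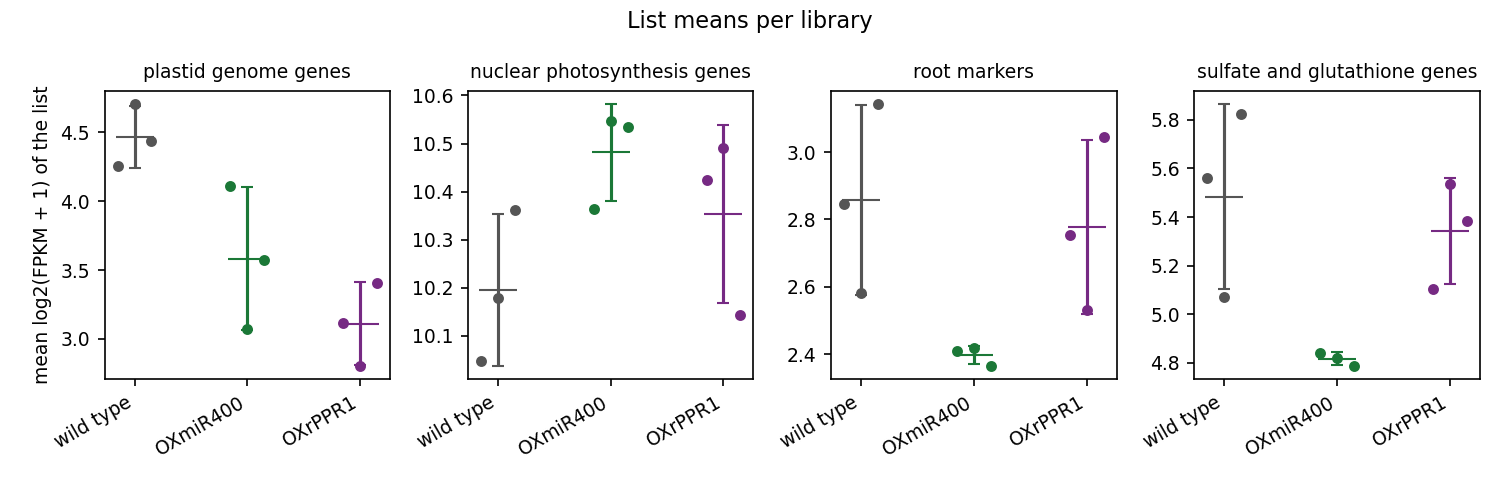
Mean log2(FPKM + 1) of 4 gene lists in each library (points), with the mean and SD of each genotype (horizontal and vertical lines); the vertical axes do not start at 0. Plastid genes lie at 4.26 to 4.71 in wild type and 2.81 to 3.41 in OXrPPR1, and root markers lie at 2.37 to 2.42 in OXmiR400.

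The lines were compared directly, since a call in 1 line alone does not show a difference between them. Of 19955 genes, 8 were higher and 5 lower in OXmiR400 than in OXrPPR1. Besides MIR400 at 9.29 ± 0.21 and PPR1 at -3.08 ± 0.16 (log2, SE), AT3G01345 differed by -6.66 ± 0.13 and AT3G05170 by -2.40 ± 0.21, the latter at 0.294 ± 0.219 FPKM in OXmiR400 and 5.84 ± 1.18 FPKM in OXrPPR1 (SD, n = 3). AT4G12545, a lipid-transfer protein gene, measured 83.8 ± 3.69 and 18.6 ± 1.298 FPKM, AT3G02620 7.54 ± 1.14 and 1.85 ± 0.015 FPKM, and AT3G23510, a cyclopropane fatty acid synthase gene, 4.82 ± 0.803 and 1.11 ± 0.055 FPKM in OXmiR400 and OXrPPR1 (SD, n = 3). The adjusted p-values of these 7 genes in limma lay between 4.32e-09 and 0.0404. MIR400, PPR1, AT3G01345 and AT3G05170 stayed called without any 1 library. The others did not without OXmiR400 replicate 1 or 2, with adjusted p up to 0.231 for AT4G12545, 0.0937 for AT3G02620 and 0.0683 for AT3G23510. AT3G02620 lost its call also without OXrPPR1 replicate 1 or 2, and AT4G12545 without any library except wild type replicates 2 and 3. The count of 13 became 7 and 8 without OXmiR400 replicates 1 and 2, and 24 with only the 6 libraries compared (9 higher, 15 lower).

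Sulfate genes were lower in OXmiR400 than in OXrPPR1 by a median of -0.35 on the log2 scale over 27 members (0 called in limma, 9 lower at unadjusted p under 0.05, 5 lower adjusted over the list alone, 0 by voom). SDI1 measured 15.2 ± 2.15 and 84.6 ± 12.1 FPKM and SULTR4;2, a vacuolar sulfate transporter gene, 7.98 ± 0.437 and 18.7 ± 4.44 FPKM (SD, n = 3). The glutathione S-transferase list had a median of -0.19 over 33 members (0 called in limma, 6 lower unadjusted, 2 lower adjusted over the list alone, 0 by voom). GSTU14 and GSTU27 differed by -0.89 ± 0.23 and -0.63 ± 0.18 (log2, SE). Root markers had a median of -0.47 over 14 members (0 called in limma, 6 lower unadjusted, 3 lower adjusted over the list alone, 0 by voom). COBL9 measured 0.807 ± 0.243 and 1.80 ± 0.244 FPKM (SD, n = 3). Plastid transcripts were higher in OXmiR400 by a median of 0.44 over 89 (0 called in limma, 17 higher unadjusted, 0 adjusted over the list alone, not tested by voom). Photosynthesis genes were higher by 0.14 over 31 (0 called in limma, 4 higher unadjusted, 1 higher adjusted over the list alone, 0 by voom), and LHCB2.1 measured 1005 ± 117 and 639 ± 107 FPKM (SD, n = 3). Camera adjusted p for these 5 lists was 6.61e-08, 0.000383, 0.00238, 9.15e-19 and 0.00238 in that order, and with an estimated correlation adjusted p = 0.830, 0.412, 0.830, 0.838 and 0.922. The plastid median was 0.18 without OXmiR400 replicate 1 and 0.68 without OXmiR400 replicate 2. The root call was lost without OXrPPR1 replicate 3 (0.0905, median -0.13), and the photosynthesis call without OXmiR400 replicate 2 (0.255), OXmiR400 replicate 3 (0.0552) or OXrPPR1 replicate 3 (0.523, median 0.05). The photosynthesis median was 0.21 without OXmiR400 replicate 1. The other 18 lists were not called (camera adjusted p = 0.0883 to 0.893), iron deficiency among them (median 0.12, adjusted p = 0.650; -0.08 without OXrPPR1 replicate 1 and 0.26 without OXrPPR1 replicate 2). Median and test, or mean and test, differed in sign for the uncalled Rf-like PPR, alternative respiratory, heat shock, reactive oxygen, ethylene and circadian lists. Without OXrPPR1 replicate 1, 8 lists were called, with retrograde (0.000132), abscisic acid (0.00163) and anthocyanin genes (0.0228) gained. Mitochondrial genes were called without OXmiR400 replicate 2 (0.00014) or OXrPPR1 replicate 3 (0.000254), dividing cell markers without OXmiR400 replicate 2 (0.0166), and iron (0.00252) and jasmonate genes (0.000197) without OXrPPR1 replicate 2.

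Genes called in both lines against wild type numbered 6, all in the same direction. Of the 114 genes called in OXmiR400, 105 (92.1%) had the same sign in OXrPPR1, to which the shared wild type libraries may contribute. GASA1 rose to 772 ± 94.1 FPKM in OXmiR400 and 833 ± 65.1 FPKM in OXrPPR1, and the noncoding RNA gene AT1G07373 to 2.86 ± 0.208 and 4.07 ± 1.81 FPKM from 0.180 ± 0.174 FPKM (SD, n = 3). UBC12 (AT3G08700), a ubiquitin-conjugating enzyme gene, fell from 1.72 ± 0.191 to 0.099 ± 0.011 and 0.142 ± 0.05 FPKM, and AT1G75945 from 7.49 ± 4.48 to 0.263 ± 0.352 and 0.038 ± 0.065 FPKM (SD, n = 3). AT1G75945 was listed at 0 in OXmiR400 replicate 2 and OXrPPR1 replicates 1 and 2. ATCG00540 and AT1G78995 fell as well. Independent lists of these sizes would share 0.009 genes higher and 0.032 lower. Simulated unchanged lines with shared wild type libraries had 0.01 in common on average and at most 1 in 100 simulations. With no change simulated and independent genes, few calls arise in either line. An overlap near 0 was thus fixed in advance, and it does not show how many of the 6 come from the shared controls. Across genes, which are not independent replicates, the log2 fold changes of the lines correlated at r = 0.589 against 0.499 in the simulations, with a covariance of 0.0642 against 0.0249, a difference of 0.0393, and 74.3% against 66.6% of genes had the same sign. The 3 wild type libraries are too few to give each line its own controls, so part of the excess may come from the shared controls. The overlap was 1 without wild type replicate 1, 3 without wild type replicate 3, and 0 at adjusted p under 0.01. In a test chosen after the data were seen, it was 2, 1 and 1 without OXmiR400 replicates 1, 2 and 3, and 0, 1 and 11 without OXrPPR1 replicates 1, 2 and 3.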

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

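The test that picked the genes below, with its limit of 0.5, was chosen after the data were seen. A gene is given here when limma called it between the lines and it lay at least 0.5 on the log2 scale from wild type in both, in opposite directions. All 3 genes found lay above wild type in OXmiR400 and below it in OXrPPR1. AT3G05945, a noncoding RNA gene on chromosome 3 at 11510090 to 11510510, differed by 5.23 on the log2 scale (adjusted p = 3.45e-08) and measured 49.6 ± 4.16 FPKM in wild type, 72.5 ± 7.33 in OXmiR400 and 0.969 ± 0.335 in OXrPPR1 (SD, n = 3). AT4G12545, a lipid-transfer protein gene, differed by 2.12 (adjusted p = 0.0404) and measured 30 ± 12.8, 83.8 ± 3.69 and 18.6 ± 1.298 FPKM (SD, n = 3, in the same order). AT3G05955, a noncoding RNA gene on chromosome 3 at 11586005 to 11586548, differed by 2.23 (adjusted p = 0.0349) and measured 1.26 ± 0.843, 5.89 ± 0.758 and 0.486 ± 0.317 FPKM (SD, n = 3). Against wild type, AT3G05945 was called lower in OXrPPR1 and not called in OXmiR400, and the other genes were called higher in OXmiR400 and not called in OXrPPR1. The positions of the noncoding genes were tested, and no other explanation was tested for these 3 genes.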

How the results depend on the processing

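The tests by voom on rebuilt units, and the overlap without 1 library of a line, were chosen after the data were seen. MIR400 in OXmiR400 and PPR1 in OXrPPR1 stayed called without any 1 library. The counts of genes called were 114, 13 and 13 (OXmiR400 and OXrPPR1 against wild type, and the lines against each other). They became 216, 39 and 24 with only the 6 libraries compared, where 101, 10 and 12 of the main calls were kept. With no filter they were 66 and 8 in the comparisons with wild type, with 61 and 7 of the main calls kept. Voom gave 8 for OXrPPR1. Replicate numbers did not pair libraries (2 of 9 residual correlations within a number above 0.1); as a block they gave 7 between the lines, and in OXrPPR1 7 higher and 3 lower against 4 and 9. Leaving out 1 library gave 8 to 194, 4 to 44 and 7 to 18 genes. Camera called 9, 4 and 5 lists, and 0, 0 and 0 with an estimated correlation (3, 2 and 1 at unadjusted p under 0.05). Fry called 4, 0 and 0, and camera on voom, which left out the organelle lists, 5 and 2 in the comparisons with wild type. Between the lines 4 to 8 lists were called without 1 library, some of them not among the 5. The overlap of 6 genes was 0 at adjusted p under 0.01 and 0 to 11 without 1 library (0 without OXrPPR1 replicate 1, 11 without OXrPPR1 replicate 3). Of the loci in the labels and their targets, 2 uncalled values turned sign in OXrPPR1 without 1 library: AT1G32583 (range -0.002 to 0.216 on the log2 scale; -0.002 without wild type replicate 2) and MIR400 (-0.206 to 0.12; 0.12 without wild type replicate 2, 0.069 without OXrPPR1 replicate 3). The median of the called retrograde list in OXmiR400 went to 0.005 without wild type replicate 1. Of the 33 calls of genes named in the comparisons above, MIR400 and PPR1 left out, 19 were kept with no filter, 28 without the variance trend and 17 with the block. No filter means more genes tested, and voom on rebuilt units had no organelle genes; for the other changes the cause was not tested. Quantile normalization kept 108 of 114 genes, median centring 106, a pseudocount of 0.1 109. Settings that need counts (other size factors, library size alone, another count test) were not run, since counts were not used here.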

Other observations

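Tests of the phosphate list, of green tissue and of gene positions were chosen after the result was seen. Phosphate starvation genes, a list added then, lay lower in OXmiR400 than in wild type in 16 of 16 members, with a median of -1.17 on the log2 scale. SPX1 and SRG3 fell, SRG3 from 84.1 ± 17.7 to 36.1 ± 9.08 FPKM (SD, n = 3), and 14 members were not called, PHT1;1, a phosphate transporter gene, measuring 51.9 ± 8.98 and 22.4 ± 2.81 FPKM. Camera gave p = 6.37e-12, and p = 0.0168 with an estimated correlation (adjusted p = 0.0673 over 4 added lists). The list also lay lower in OXrPPR1 (median -0.26, 13 of 16 below 0, camera adjusted p = 0.0256, 0.805 with an estimated correlation). In OXmiR400 it lay lower than in OXrPPR1 (median -0.62, 16 of 16 below 0, 0 called in limma). There camera gave adjusted p = 3.1e-11, and 0.0685 with an estimated correlation. Root markers lay lower in OXmiR400 than in wild type too (median -0.51), and a smaller share of root tissue was not tested for the phosphate list. The set may be lower in OXmiR400, a hypothesis found and tested on the same libraries.

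Nuclear genes of the mitochondrial respiratory complexes, 60 in all, had medians of 0.025 and 0.038 on the log2 scale in OXmiR400 and OXrPPR1 (0 called in limma), with camera p = 0.101 and 0.02029, and p = 0.599 and 0.462 with an estimated correlation. Over the 4 added lists, camera also gave p = 0.00269 for 308 cytosolic ribosomal genes (p = 0.587 with an estimated correlation) and p = 0.730 for 217 pentatricopeptide repeat genes in OXmiR400.

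Plastid and mitochondrial transcripts were lower in both lines. Less carry-over of RNA without a poly(A) tail was tested on 53 nuclear snoRNA and snRNA genes. Their median was -0.059 in OXrPPR1 (bootstrap interval -0.194 to 0.074) and 0.247 in OXmiR400 (0.081 to 0.301). They did not drop as less carry-over was predicted to make them. Whether they carry over as organelle RNA does was not tested, so less carry-over cannot be excluded. The nuclear photosynthesis list lay at 0.149 in OXrPPR1 (0.086 to 0.215, 31 genes), and at 0.04 to 0.26 without 1 library. It did not fall as a lower share of green tissue in that line was predicted to make it. Per library the list averaged 10.425, 10.491 and 10.142 in OXrPPR1 and 10.047, 10.178 and 10.362 in wild type, which overlap. Whether these genes follow green tissue alone was not tested, so a lower share cannot be excluded. The bootstrap intervals resample genes, which vary together, so they leave out the spread between libraries. A difference in organelle RNA itself is also possible, and the estimated-correlation test did not call these lists.

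Sulfate genes were lower in OXmiR400, as were root markers. A single wild type library as the source is argued against, since the median stayed at or below -0.355 without each of them. With the root marker mean as a covariate the median went from -0.511 to -0.168 (bootstrap interval over genes -0.454 to -0.102, camera adjusted p = 0.00227). A smaller share of root tissue and a change in sulfate genes cannot be told apart. The median with the covariate lies between the bounds set for the 2 readings before the result was seen. The root markers themselves differ between genotypes, and their mean hardly varied within OXmiR400 (SD 0.028, against 0.281 in wild type and 0.258 in OXrPPR1).

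Called genes between the lines included 3 within 2 Mb at the start of chromosome 3 (129138 to 1468400). Random positions gave as many in a share of 0.2288 of 10000 draws (permutation p). A gain or loss of that whole segment is argued against by the median of -0.009 over its 484 tested genes (bootstrap interval over genes -0.026 to 0.008). The noncoding RNA genes AT3G29644, AT3G05945 and AT3G05955, called between the lines, lie within 0.1 Mb of chromosome 3 (11498879 to 11586548), at -1.66, 5.23 and 2.23 on the log2 scale, among 6 tested genes. Random positions gave as many in a window of that length in 9 of 10000 draws (permutation p = 0.001), with the length chosen to suit these genes, so the p is too small by an unknown amount, and what groups them was not tested.

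Other splits of the 6 libraries of each comparison number 10, real one included, too few for a share under 0.05. As many genes as in the real split were called in 1 split for OXmiR400 against wild type (114, highest other 2), 2 for OXrPPR1 against wild type (13, highest other 114) and 1 between the lines (13, highest other 5). For lists the numbers were 4 (9, highest other 9), 9 (4, highest other 8) and 8 (5, highest other 10). Camera at the preset correlation thus called as many lists in some wrong groupings as in the real one. Its list calls alone do not show a difference between genotypes. The split with 114 genes sets wild type replicates 1 and 3 and OXrPPR1 replicate 3 against the rest, which points to a structure of the samples apart from genotype.

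Some genes were present in some libraries and near 0 in others, with limits chosen after the data were seen. AT1G66820, a glycine-rich protein gene, was listed at 25.4, 0 and 0 FPKM in the wild type libraries, 27.1, 25.3 and 21.2 in OXmiR400 and 0 in the 3 of OXrPPR1. AT1G06540 was listed at 26.7, 12.3 and 23.1 FPKM in wild type, 0, 0 and 0.032 in OXmiR400 and 0.129, 0.121 and 13.6 in OXrPPR1. GGPS1 was listed at 0, 1.97 and 4.72 FPKM in OXrPPR1.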
